A study of Mus musculus with 16 samples.

How the data were processed

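The libraries were made from mouse liver total RNA with the Illumina TruSeq Stranded kit and Ribo-Zero Gold depletion, per the labels' protocols. The deposited table holds raw read counts per Ensembl gene for each liver, which the authors did not normalize, as its whole numbers and unequal library totals show. Per the submitters' processing notes, the genome build was GRCm38 and the tools were STAR 2.5.4a, featureCounts 1.5.1 and DESeq2; the role of each tool, the strand setting, the handling of multiply mapped reads and the annotation release are not given in the sources used here. All 16 columns of the table matched a sample label, and 0 columns were left unmapped. The table lists 53801 gene IDs, of which 53620 had a symbol and 53706 a position in a GENCODE annotation of the same build.

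Groups were taken from the diet and genotype in the sample titles. The labels give each liver its own animal number and no pairing, so livers were treated as separate animals and no block was fitted. Total counts ran from 11938596 to 23250885, so a count of 3 corresponds to between 0.129 and 0.251 CPM. Counting error is only part of the spread, and all tests use the spread between livers. For the 24 pairs of livers within groups, chi-square per degree of freedom over genes with at least 10 counts was 12.28 to 125.6, so no pair agreed within sampling noise. The correlation of log2 CPM across genes was 0.9207 to 0.9838 in these pairs.

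The tests, gene lists, naming rule and most alternatives were chosen before the data were examined. Genes were filtered with filterByExpr (minimum count 10), which left 14351, and scaled with TMM. A model with a term for each of the 4 groups over all 16 livers was fitted with edgeR 4.0.16 in R 4.3.3 and tested by quasi-likelihood F tests for the 4 comparisons between groups and for the interaction. The common biological coefficient of variation was 0.247. p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Standard errors were taken as the absolute log2 fold change over the square root of F. CPM values use the TMM-scaled library sizes. Degs1 was also tested by a two-sided exact permutation test of log2(CPM + 1) over the 70 assignments of 8 livers.

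The 44 gene lists, covering lipid and glucose metabolism, stress, inflammation, fibrosis, cell types and possible contamination, were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 and adjustment over the lists of a comparison. They were tested again with an estimated correlation and with fry, which tests whether the members of a list move one way on balance. None of the camera calls held with an estimated correlation. List medians are of edgeR fold changes, except those from leave-one-out fits and other alternatives, which are of voom fold changes. In brackets after a list median stand the members past the test over all genes and then those past it when adjusted over the list alone.

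The text names Degs1. For each comparison between groups it names up to 10 genes in each direction with the largest fold change among those called, with a mean log2 CPM of at least 2 and no overlap between groups, gene models named only by number being passed over. It also names up to 4 members of each list with the smallest p, and 10 genes of the interaction with the smallest p at the same mean. Some of these genes were left out for length, and a gene outside the rule is said to be so.

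Alternatives were DESeq2 1.42.0, other scaling factors, other filters, limma-voom with and without quality weights, fits of only the groups compared, other thresholds, removal of abundant features, and each library left out in turn. Leaving out a library brings the smallest group to 3, and the filter, run again, then passed 14535 to 14715 genes. Camera was therefore also run with the genes tested in all libraries kept. This, an alternative without 2 libraries standing apart, one with the log2 share of counts on sense-intronic and unconfirmed transcripts as a covariate, and one with offsets for transcript length and GC (known for 99.9% of genes tested) were added after seeing the data.

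The model was tested on simulated counts with the real means, dispersions and library sizes and 200 changed genes. For changes of 1 on the log2 scale, 53.5% were recovered for knockout on chow (14267 genes), 48% for knockout on the high-fat diet (14234), 53.1% for diet in controls (14193), 45.5% for diet in knockouts (14239) and 20% for the interaction (14243). For changes of 2 on the log2 scale the shares were 87.9%, 87.9%, 81.6%, 82% and 74.7%, with 12, 5, 10, 3 and 5 false calls. A list shifted by 0.5 was called in each case, with 0 other lists. Each gene was drawn on its own, so the simulated lists carry no correlation between members. The 0 therefore says nothing about false list calls in the livers.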

Results

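Gene-level RNA-seq read counts were available for 16 mouse livers in 4 groups of 4. The groups cross genotype (control or a liver-specific knockout of Degs1) with diet (normal chow or a high-fat diet). Degs1 encodes dihydroceramide desaturase, the enzyme that puts the double bond into the ceramide backbone. The total count per library was 14417061 to 23250885 in the chow controls and 11938596 to 18235419 in the chow knockouts. It was 14020001 to 18728453 in the high-fat controls and 13572441 to 16559537 in the high-fat knockouts. Nothing in the labels ties livers to batches, and the animal numbers in the sample titles run from 61 to 92 on the high-fat diet and from 179 to 220 on chow. Each range therefore holds livers of a single diet, so no comparison between diets within a range was possible. The numbers also separate the genotypes within each diet. Chow knockouts were at 179 to 187 and chow controls at 194 to 220, and high-fat controls at 61 to 76 and high-fat knockouts at 82 to 92. A difference that goes with animal number therefore cannot be told apart from genotype either.

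The libraries differed in the share of counts on sense-intronic transcripts and transcripts of unproven status, read here as a measure of unspliced RNA. The share was 0.0346% ± 0.00624 (SD, n = 4) in chow controls, 0.0664% ± 0.0218 in chow knockouts, 0.09% ± 0.0651 in high-fat controls and 0.171% ± 0.0134 in high-fat knockouts (SD, n = 4 each). High-fat control 3 was at 0.0218% and high-fat control 1 at 0.164%. Malat1, a nuclear long noncoding RNA, was at 157.7 CPM (read counts scaled by library size) in high-fat control 3. It was at 4236 CPM in high-fat control 1 and 4238 CPM in high-fat knockout 2. The first principal component held 36.2% of the variance. On the second component high-fat control 3 was at -64.7 and chow knockout 1 at 51.1, with the other libraries between -23.9 and 26.2.

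**Figure D1:**
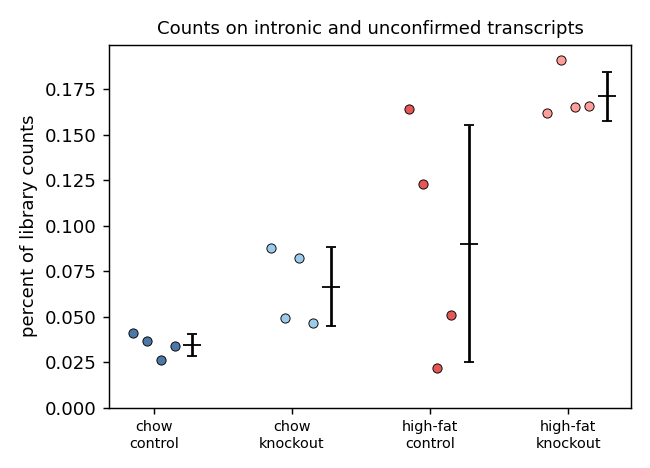
Percent of each library's counts on sense-intronic and unconfirmed transcripts (y axis) in the 4 groups (x axis), with points for libraries and bars for the mean and SD. The high-fat knockouts lie between 0.162% and 0.191% and the high-fat controls between 0.0218% and 0.164%.

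Degs1 was lower in every knockout liver than in every control liver on the same diet. Degs1 (ENSMUSG00000038633) lies on chromosome 1 from 182275772 to 182282804 on the minus strand of GRCm38, and the counts cover the whole gene. On chow, the controls were at 85.5, 80.4, 87.9 and 84.9 CPM and the knockouts at 39.3, 39.3, 37.4 and 35.9 CPM. The means were 84.7 ± 3.13 and 38 ± 1.65 CPM (SD, n = 4 each). The log2 fold change was -1.16 with a standard error (SE) of 0.17 (edgeR adjusted p = 0.0123). On the high-fat diet, the controls were at 60.2, 62.2, 101 and 70.3 CPM and the knockouts at 41.6, 28.1, 26.1 and 29.2 CPM. The means were 73.4 ± 18.9 and 31.3 ± 7.01 CPM (SD, n = 4 each), with a log2 fold change of -1.23, SE 0.17 (edgeR adjusted p = 0.00376). The two-sided exact permutation p was 0.0286 on each diet, the smallest that 4 against 4 allows. The chow call was lost without chow control 1 (log2 fold change -1.15, edgeR adjusted p = 0.0568), 3 (-1.13, 0.0764) or 4 (-1.15, 0.0575). It was also lost without chow knockout 1 (-1.16, 0.0692), 2 (-1.17, 0.0793), 3 (-1.14, 0.118) or 4 (-1.12, 0.0796), with fold changes that barely moved.

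**Figure D2:**
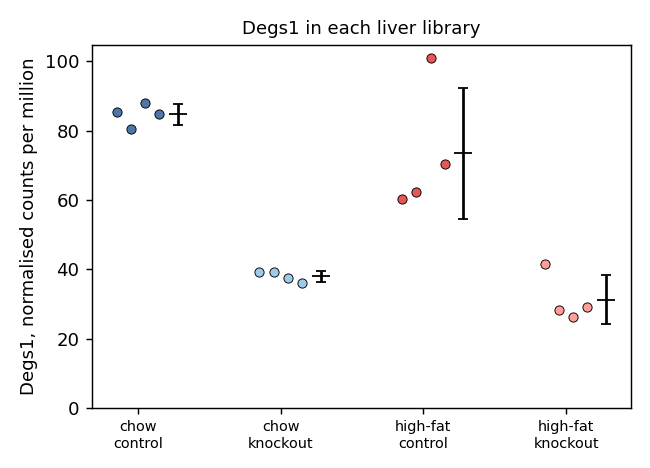
Degs1 in normalised CPM (y axis) in each liver library of the 4 groups (x axis), with points for libraries and bars for the mean and SD. The chow knockouts lie between 35.9 and 39.3 CPM and the chow controls between 80.4 and 87.9 CPM.

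The next comparison asks how loss of Degs1 changed the liver transcriptome on chow. Besides Degs1, Srebf1 was lower. Srebf1 encodes a transcription factor that drives fatty acid synthesis, and it stood at 154 ± 26.3 CPM in knockouts and 490 ± 174 CPM in controls (SD, n = 4 each; log2 fold change -1.67, SE 0.24, edgeR adjusted p = 0.0123). The Srebf1 call was lost without chow control 3 and without chow knockout 1, 2, 3 or 4. It was also lost with only the groups compared (log2 fold change -1.65, edgeR adjusted p = 0.115), without high-fat control 3 and chow knockout 1 together (-1.62, 0.0563) and with the unspliced share as a covariate (-1.67, 0.0543), with log2 fold changes from -1.86 to -1.46 over all alternatives. Oat, a pericentral ornithine aminotransferase, had a log2 fold change of -0.96, SE 0.18, and did not pass (edgeR adjusted p = 0.128). Lpl, the lipoprotein lipase, had 1.01, SE 0.26 (0.353). In the sphingolipid synthesis list, Cers2, a ceramide synthase, had -0.24, SE 0.13 (0.543), and Ormdl3, a regulator of serine palmitoyltransferase, had -0.30, SE 0.15 (0.539). Of 14351 genes tested, 0 rose and 2 fell by edgeR, 1366 had an unadjusted p under 0.05, and the groups did not overlap for 6.34% of genes against 2.86% by chance. Here and below, 2.86% is the mean over all assignments of the livers. Genes move together, so the share may vary much between assignments, and it was not computed for other splits. An excess over 2.86% therefore does not exclude chance. DESeq2 called 39 genes and limma-voom with quality weights 4. The count was 1 without chow control 1 or 4 and 0 without chow control 3 or without any 1 of chow knockouts 1, 2, 3 and 4. It was 4 without chow control 2 or high-fat control 3, and 0 with the unspliced share as a covariate, added after seeing the data.

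Among the gene lists, 8 of 44 passed camera in the chow knockout, 1 higher and 7 lower, 0 of which passed with an estimated correlation. The list of mitochondrially encoded messages was the higher one, with a median log2 fold change of 1.05 over the 8 genes tested of 13. Members not tested had almost no counts, such as mt-Co2 and mt-Co3 with 5.29e-06% and 4.16e-06% of all counts, against 1.18% for mt-Co1. The list therefore covers only part of the mitochondrially encoded messages. Of its members 0 passed over all genes and 7 rose when adjusted over the list alone (camera adjusted p = 1.06e-08; adjusted p = 0.379 with an estimated correlation). mt-Nd1 and mt-Co1, subunits of respiratory complexes, had log2 fold changes of 0.85, SE 0.24, and 0.77, SE 0.22 (edgeR adjusted p = 0.353 each). mt-Nd6 had 2.55, SE 0.51 (0.171), but it overlaps mt-Nd5 on the other strand and the strand setting of the counting is not given in the sources used here. The respiratory chain list was lower, with a median of -0.18 over 42 genes and 0 members past the test over all genes or adjusted over the list alone. Its camera adjusted p was 2.13e-05, and adjusted p = 0.955 with an estimated correlation. The ribosomal protein (median -0.17), acute phase (-0.30), interferon (-0.18), Kupffer cell (-0.40), pericentral (-0.20) and fetal liver (-0.27) lists were lower too, with 0 members past the test over all genes and adjusted p = 0.955 with an estimated correlation each. Adjusted over the list alone, 1 interferon gene, Oasl1 (-0.76, SE 0.18, edgeR adjusted p = 0.276 over all genes), 1 pericentral gene and 1 acute phase gene passed, the last of them higher. The list of markers of fat and pancreas was not called on chow, with a median of -1.75 over the 2 genes tested (0 fell over all genes, 1 adjusted over the list alone; camera adjusted p = 0.382, adjusted p = 0.955 with an estimated correlation). Its mean log2 CPM was 0.971 ± 0.4 in knockouts and 2.4 ± 0.41 in controls (SD, n = 4 each), with no overlap between the groups (exact permutation p = 0.0286, adjusted p = 0.315 over the 44 lists).

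Several chow list calls rested on single libraries. The acute phase list was not called without chow control 3, the pericentral list without chow knockout 4, nor the ribosomal list without chow knockout 3. The Kupffer cell list was not called without chow control 1, chow control 3 or chow knockout 2, and the interferon list without any of these or chow knockout 4. The fetal liver list was not called without chow control 1, 2 or 4, chow knockout 2, 3 or 4, or high-fat control 3. With the same genes tested as in all libraries it was called without chow control 2, chow knockout 4 or high-fat control 3. The leave-one-out medians were -0.392 to -0.164 for acute phase, -0.252 to -0.122 for pericentral, -0.252 to -0.101 for ribosomal, -0.523 to -0.12 for Kupffer cell, -0.273 to -0.0782 for interferon and -0.451 to -0.172 for fetal liver genes. Some called medians grew by over 1.5 times on the voom scale, from -0.251 to -0.392 for acute phase without chow control 1 and from -0.326 to -0.523 for Kupffer cell genes without chow control 2. With the unspliced share as a covariate the respiratory chain median went on the voom scale from -0.172 to 0.0166 and was not called, and the ribosomal median went from -0.171 to 0.15.

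The same comparison on the high-fat diet asks what loss of Degs1 did in livers under a fat load. Collagen genes rose in the knockout: Col1a1 was at 48.1 ± 21.8 CPM against 8.08 ± 1.61 in controls, and Col1a2 at 58.9 ± 22.5 against 19.5 ± 3.27 CPM (SD, n = 4 each). The log2 fold changes were 2.57, SE 0.35, for Col1a1 (edgeR adjusted p = 0.00376) and 1.59, SE 0.27, for Col1a2 (0.0257). Col5a2, another fibrillar collagen, rose by 1.38, SE 0.25 (0.0415), and Adamts2, which trims procollagens, by 1.15, SE 0.20 (0.0335). Gstm3, a glutathione transferase, rose by 2.52, SE 0.32 (0.00376), and Phlda3, a p53 target, by 2.42, SE 0.37 (0.0129). Ano10, of the anoctamin family, rose by 0.92, SE 0.15 (0.0191), and Rnf213, an interferon-responsive ubiquitin ligase, by 0.91, SE 0.15 (0.0257). Emp1, a membrane protein chosen after its values were seen, rose by 1.45, SE 0.27 (0.0427).

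Among the genes that fell in the high-fat knockout, Oat was at 657 ± 122 CPM in knockouts and 1381 ± 55.6 in controls (SD), log2 fold change -1.07, SE 0.18 (n = 4 each, edgeR adjusted p = 0.0257). Lhpp, a pericentral phosphatase, had -0.83, SE 0.16 (0.0455), and Gna14, a G protein subunit, had -1.07, SE 0.20 (0.0479). Cyp2c37, a cytochrome P450, had -1.44, SE 0.26 (0.0398), and the major urinary proteins Mup15 and Mup11 had -3.41, SE 0.63 (0.0415), and -2.15, SE 0.38 (0.0335). Values of Gstm3, Cyp2c37 and the Mup genes are uncertain, because close paralogs could share reads and the handling of multiply mapped reads is not given in the sources used here. In all, 9 genes rose and 7 fell, 3066 genes had an unadjusted p under 0.05, and the groups did not overlap for 13.2% of genes against 2.86% by chance. The split was 27 up and 7 down with upper-quartile factors, 228 and 350 with DESeq2, 21 and 10 with limma-voom, and 13 and 1 with length and GC offsets, which held 6 of the 16. Of the 16, 9 were called without high-fat control 3 and chow knockout 1 together. A fit of only the high-fat groups called 1 gene, Mup15. Degs1, Col1a1 and Gstm3 were the 3 genes called in all 16 leave-one-out fits. The call was lost in 3 of them for Phlda3, 4 for Ano10 and Oat, 5 for Col1a2 and Rnf213, 8 for Adamts2, Mup11 and Cyp2c37, 10 for Mup15, 12 for Col5a2 and Emp1, 13 for Gna14 and 14 for Lhpp. The count was 8 without chow control 2, 26 without chow control 3, 10 without chow knockout 3, 5 without high-fat control 2, 4 without high-fat control 4, 6 without high-fat knockout 1, 3 without high-fat knockout 2 and 31 without high-fat knockout 4. With the unspliced share as a covariate it was 0, and the log2 fold changes were 2.67 for Col1a1, 2.64 for Gstm3 and -0.92 for Degs1 (edgeR adjusted p = 0.0535 each).

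**Figure D3:**
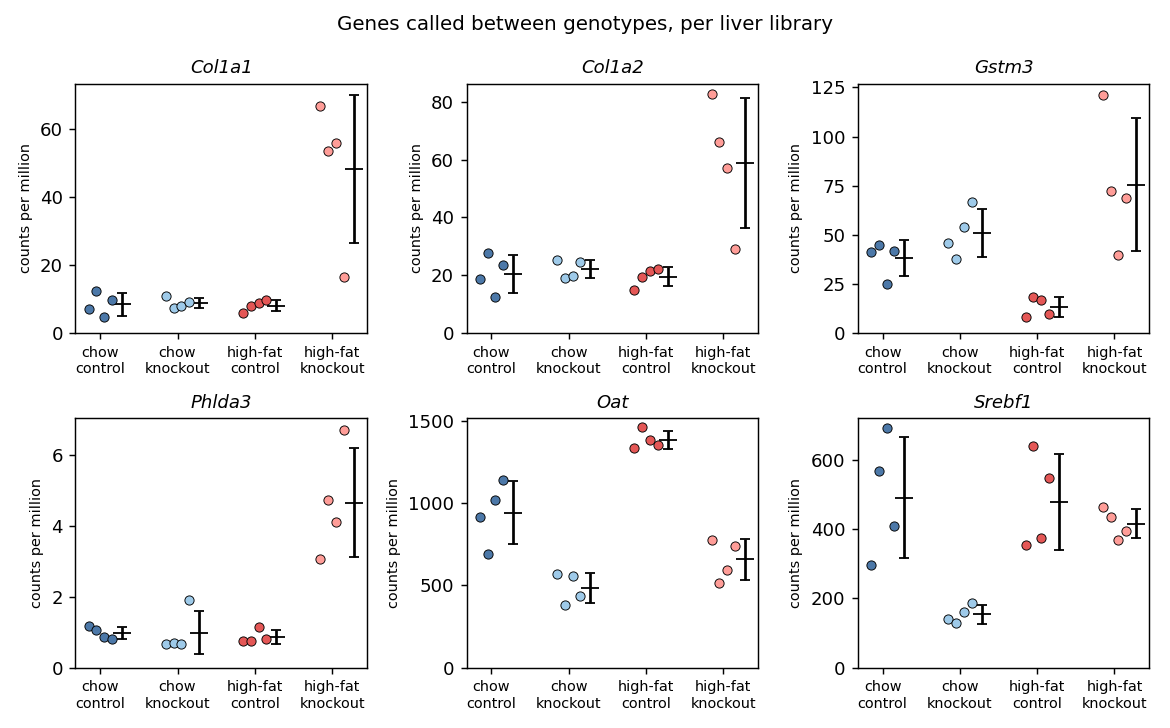
CPM values (y axes) of 6 genes called between genotypes in each liver library of the 4 groups (x axes), with points for libraries and bars for the mean and SD. Col1a1 averages 48.1 CPM in the high-fat knockouts and 8.08 CPM in the high-fat controls.

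In the high-fat knockout, 18 of 44 lists passed camera, 6 higher and 12 lower, and 0 of them passed with an estimated correlation. In the fibrosis and matrix list 3 of 32 genes rose over all genes and 21 adjusted over the list alone, with a median of 0.72 (camera adjusted p = 4.31e-12; adjusted p = 0.290 with an estimated correlation). Its Col3a1 had 1.34, SE 0.27 (edgeR adjusted p = 0.0584). In the interferon list 0 of 28 genes rose over all genes and 19 adjusted over the list alone, with a median of 0.77 (adjusted p = 0.290 with an estimated correlation). Gbp3, a guanylate-binding protein, had 1.13, SE 0.25 (edgeR adjusted p = 0.0736), and Oasl2 had 1.01, SE 0.24 (0.0923). In the inflammatory list 0 of 22 rose over all genes and 14 adjusted over the list alone, with a median of 0.78 (adjusted p = 0.290 with an estimated correlation). Tnfaip3 and Relb, both in the NF-kB pathway, had 1.03, SE 0.27 (edgeR adjusted p = 0.0977), and 1.21, SE 0.33 (0.0981). In the p53 list 1 of 27 rose, and 7 adjusted over the list alone, with a median of 0.33 (adjusted p = 0.117 with an estimated correlation). Its Gdf15, a stress-induced hormone, had 1.74, SE 0.35 (edgeR adjusted p = 0.0584).

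The other higher lists in the high-fat knockout were recruited macrophage markers (median 0.90, 0 of 17 over all genes, 4 adjusted over the list alone) and cell cycle (median 0.405, 0 of 27, 2 adjusted over the list alone). With an estimated correlation they had adjusted p = 0.513 and adjusted p = 0.453. Gpnmb had 3.89, SE 0.855 (edgeR adjusted p = 0.0736), Itgax 1.51, SE 0.37 (0.0953), and Mki67 1.59, SE 0.33 (0.0664). The macrophage list was no longer called without high-fat control 1 or high-fat knockout 1, nor the cell cycle list without high-fat control 1, with medians over the 16 leave-one-out fits of 0.44 to 0.94 and 0.29 to 0.79. With the same genes tested as in all libraries, the macrophage list was called without high-fat knockout 1 (camera adjusted p = 0.0491). Cygb, a stellate cell gene, had 0.72, SE 0.16 (0.0726), while its list was not called (median 0.03, camera adjusted p = 0.256).

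Lists that were lower in the high-fat knockout were led by the respiratory chain and the ribosomal proteins. Of the respiratory chain list 0 of 42 genes fell over all genes and 40 adjusted over the list alone, with a median of -0.59 (camera adjusted p = 7e-20; adjusted p = 0.290 with an estimated correlation). Ndufv2 and Ndufb3, complex I subunits, had -0.77, SE 0.19, and -0.79, SE 0.19 (edgeR adjusted p = 0.0923 each). Of the ribosomal list 0 of 46 fell over all genes and 38 adjusted over the list alone, with a median of -0.57 (camera adjusted p = 3.74e-14; adjusted p = 0.349 with an estimated correlation). Rps18 had -0.75, SE 0.24 (edgeR adjusted p = 0.113). With the unspliced share as a covariate the respiratory chain median went on the voom scale from -0.539 to -0.193 and was still called, while the ribosomal median went from -0.481 to -0.0248 and was not called (camera adjusted p = 0.86). High-fat control 3, the library with the unspliced share of 0.0218%, had Ndufv2 at 173 CPM against 83.1 to 90.1 CPM in the other high-fat controls. Without it the medians were -0.293 for the respiratory chain and -0.21 for the ribosomal list, both still called, against -0.539 and -0.481 with all libraries. With length and GC offsets, added after seeing the data, the medians were -0.183 and -0.139, and both lists were still called.

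Metabolic lists were lower as well, by smaller amounts. Fatty acid oxidation had a median of -0.44 (0 of 30 over all genes, 15 adjusted over the list alone), xenobiotic cytochromes -0.43 (1 of 30, 10) and lipoproteins -0.36 (0 of 27, 12). With an estimated correlation these had adjusted p = 0.349, adjusted p = 0.349 and adjusted p = 0.290. Male-biased genes had -0.43 (1 of 26, 7), periportal genes -0.25 (0 of 24, 2) and bile acid genes -0.23 (0 of 27, 4), each with adjusted p = 0.290 with an estimated correlation. Sphingolipid synthesis had -0.36 (0 of 11, 4) and pericentral genes -0.10 (2 of 24, 2), each with adjusted p = 0.349 with an estimated correlation. Ormdl1 and Ormdl2, regulators of serine palmitoyltransferase, had -1.02, SE 0.27 (edgeR adjusted p = 0.0981), and -0.52, SE 0.17 (0.114). The sphingolipid list was not called without high-fat control 4 or high-fat knockout 3, nor the pericentral list without high-fat control 1 or 2, with leave-one-out medians of -0.401 to -0.239 and -0.164 to -0.0751. The ER chaperone (-0.27) and lysosome (-0.14) lists had 0 members past the test over all genes or adjusted over the list alone, with adjusted p = 0.425 and adjusted p = 0.544 with an estimated correlation. The lysosome list was not called without high-fat control 3 (medians -0.19 to -0.0133, the first without high-fat control 2, with -0.162 without high-fat control 1). With the same genes tested as in all libraries it was also lost without chow control 2, chow knockout 1 or high-fat knockout 4. Without high-fat control 3 the medians were -0.192 for fatty acid oxidation, -0.186 for xenobiotic cytochromes and -0.213 for lipoproteins, against -0.41, -0.402 and -0.32 on the same voom scale with all libraries. Without high-fat knockout 3 male-biased genes were at -0.716 against -0.434. The fatty acid oxidation (-0.0821), sphingolipid (-0.0896) and lysosome (-0.0146) lists were not called with the unspliced share as a covariate.

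**Figure D4:**
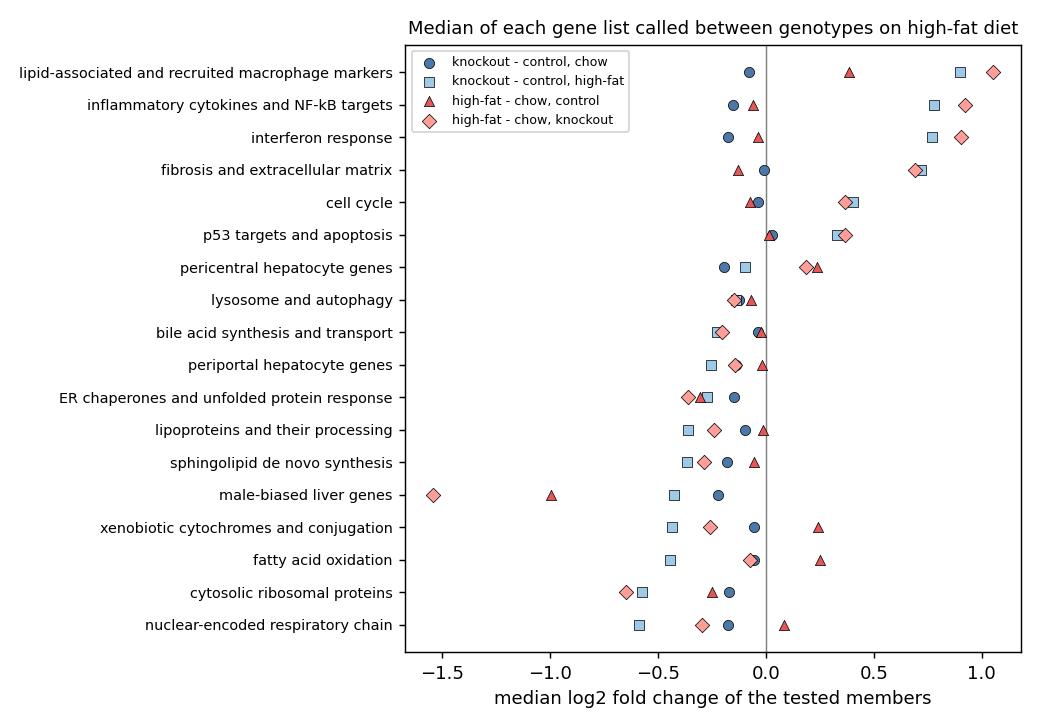
Median log2 fold change (x axis) of the tested members of each gene list called between genotypes on the high-fat diet (y axis), with a marker for each of the 4 comparisons. The respiratory chain median is -0.587 between genotypes on the high-fat diet and -0.176 on chow.

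The high-fat diet was then compared with chow in control livers. Cyp2b9, a female-biased cytochrome P450, rose from 0.124 ± 0.135 to 117 ± 54.1 CPM (SD, n = 4 each; log2 fold change 9.61, SE 0.71, edgeR adjusted p = 1.08e-06). Acnat2, an acyl transferase, rose by 2.34, SE 0.23 (6.56e-05), Cyp17a1, a steroid hydroxylase, by 2.90, SE 0.51 (0.00856), and Cyp3a59 by 2.025, SE 0.44 (0.0238). The fat droplet protein Plin4 rose by 2.49, SE 0.61 (0.0439), and the fatty acid transporter Cd36 by 1.74, SE 0.43 (0.0447). Sema5b and Omd rose by 1.89, SE 0.43 (0.03), and 1.82, SE 0.33 (0.00909). The noncoding RNAs Ctcflos and Firre rose by 2.11, SE 0.38 (0.00909), and 1.94, SE 0.39 (0.0149).

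Among genes that fell with the diet in controls, Adgrf1, an adhesion receptor, had a log2 fold change of -4.20, SE 0.69 (edgeR adjusted p = 0.00587), and Fabp5, a fatty acid binding protein, -3.70, SE 0.59 (0.00557). Serpina1e, a male-biased secreted protease inhibitor, had -3.40, SE 0.62 (0.00909), and Cyp4a12b -2.57, SE 0.52 (0.0158). The protease Prss8 had -2.60, SE 0.32 (0.000774) and Tgm1 -2.00, SE 0.41 (0.017). Csad, an enzyme of taurine synthesis, had -2.15, SE 0.46 (0.0228), Acacb, which makes malonyl-CoA, -2.14, SE 0.33 (0.00493), and the insulin receptor substrate Irs2 -1.80, SE 0.34 (0.0119). Cyp2b9, Cyp3a59, Cyp4a12b, Serpina1e and the Gstm genes have close paralogs, so their values are uncertain.

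**Figure D5:**
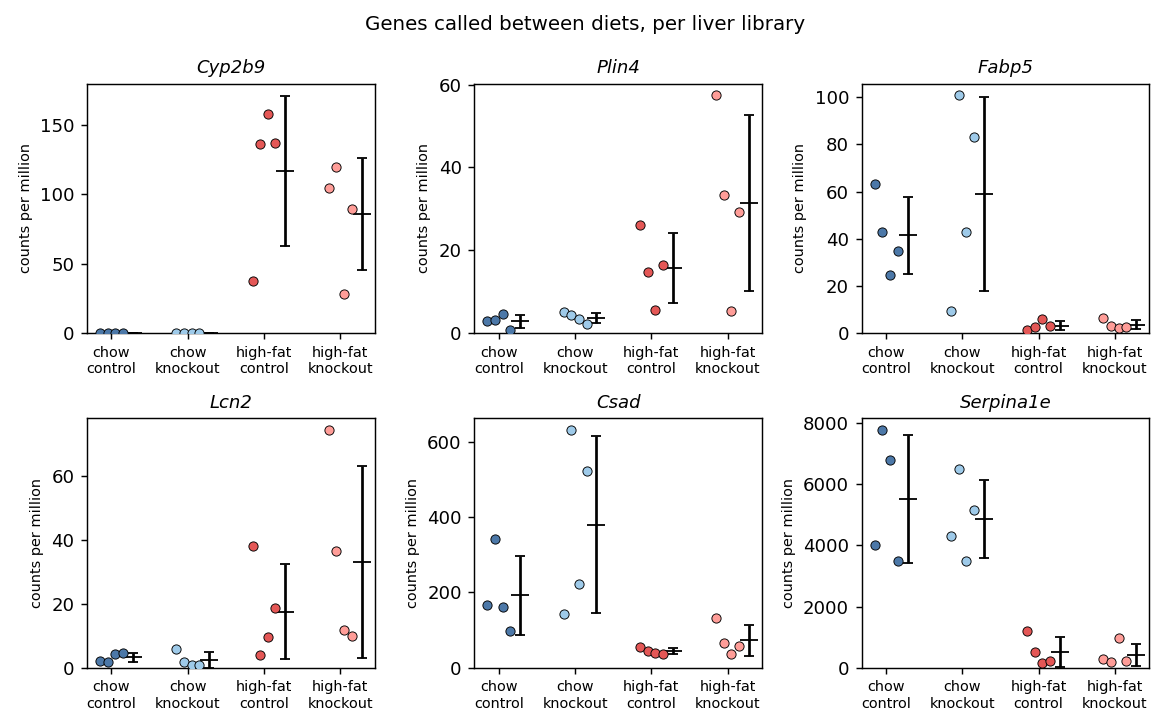
CPM values (y axes) of 6 genes called between diets in each liver library of the 4 groups (x axes), with points for libraries and bars for the mean and SD. Cyp2b9 averages 0.124 CPM in the chow controls and 117 CPM in the high-fat controls.

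In control livers 135 genes rose and 127 fell with the diet, 2449 genes had an unadjusted p under 0.05, and the groups did not overlap for 7.23% of genes against 2.86% by chance. The split was 170 up and 100 down with upper-quartile factors, 469 and 250 with DESeq2, 72 and 106 with limma-voom, and 484 and 673 with the unspliced share as a covariate, so the balance rests on the setting. Of the 262 genes, 75 were called in all 16 leave-one-out fits. The count was 160 without chow control 1, 100 without chow control 2, 161 without chow control 3, 113 without chow control 4, 163 without high-fat control 1, 130 without high-fat control 2 and 955 without high-fat control 3. Without high-fat control 3 and chow knockout 1 together, left out after seeing the data, it was 1219, and with the covariate 1157, which held 193 of the 262. Among the genes named, the call was lost in 11 of the 16 leave-one-out fits for Plin4 and Cd36, 5 for Sema5b, 4 for Cyp3a59 and Acly, 3 for Csad, Tgm1 and Gstm3 and 1 for Firre. With limma-voom the calls of Plin4, Cd36, Firre and Sema5b were lost, and in a fit of only the control groups those of Cyp17a1, Plin4, Cyp3a59, Firre, Sema5b, Tgm1, Irs2, Rdh11 and Gckr. With the covariate those of Plin4, Sema5b and Tgm1 were lost.

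In controls, 11 of 44 lists passed camera between the diets, 4 higher and 7 lower, 0 of which passed with an estimated correlation. In the cholesterol synthesis list 7 of 26 genes fell, and 21 adjusted over the list alone, with a median of -0.85 (camera adjusted p = 3.86e-17; adjusted p = 0.465 with an estimated correlation). Pmvk, a mevalonate pathway kinase, had -1.52, SE 0.27 (edgeR adjusted p = 0.00909), and Rdh11 -1.70, SE 0.32 (0.0101). In the fatty acid synthesis list 5 of 21 fell, and 11 adjusted over the list alone, with a median of -0.76 (adjusted p = 0.465 with an estimated correlation). Acss2 and Acly, which make acetyl-CoA, had -1.68, SE 0.30 (edgeR adjusted p = 0.00875), and -1.21, SE 0.26 (0.0224). In the male-biased list 9 of 26 fell, and 16 adjusted over the list alone, with a median of -0.99 (camera adjusted p = 4.86e-17; adjusted p = 0.216 with an estimated correlation). Cyp4a12a, a fatty acid hydroxylase, had -1.74, SE 0.26 (edgeR adjusted p = 0.0046). In the female-biased list 6 of 18 rose, and 8 rose and 2 fell adjusted over the list alone, with a median of 1.01 (adjusted p = 0.611 with an estimated correlation). Its Hao2 was at 3.04 ± 2.56 CPM against 0.0956 ± 0.115 CPM (SD, n = 4 each; edgeR adjusted p = 0.0119).

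The other lists called in controls were as follows. NRF2 genes had a median of -0.18, with 2 of 28 falling and 5 adjusted over the list alone (adjusted p = 0.611 with an estimated correlation). The 2 were Gstm1, -1.12, SE 0.19 (edgeR adjusted p = 0.00614), and Gstm3, -1.53, SE 0.31 (0.0162). Ribosomal proteins had a median of -0.25 (3 of 46 fell, 7 adjusted over the list alone) and the PPAR gamma list 1.49 (2 of 7 rose, 2), each with adjusted p = 0.711 with an estimated correlation. Fatty acid oxidation had 0.25 (0 of 30, 0) and PPAR alpha targets 0.11 (0 of 25, 2), each with adjusted p = 0.736 with an estimated correlation. Insulin signalling had -0.16 (2 of 31, 3) and ER chaperones -0.31 (0 of 25, 0), each with adjusted p = 0.611 with an estimated correlation. Without high-fat control 3, the fatty acid oxidation, PPAR alpha, PPAR gamma, female-biased and insulin lists were not called, nor the PPAR alpha list without chow control 2 or the PPAR gamma list without high-fat control 2. With the same genes tested as in all libraries, the PPAR gamma list was called without high-fat control 2 but not without chow control 2. Their leave-one-out medians were 0.0807 to 0.359, 0.217 to 0.341 (0.25 on the same voom scale with all libraries), 1.18 to 1.9, 0.663 to 1.13 and -0.217 to -0.0613 in that order. On the same scale the NRF2 median was -0.204 and went to -0.0805, -0.126 and -0.38 without high-fat control 1, 2 and 3, and the ribosomal median was -0.317 and went to -0.201, -0.162 and -0.565. The insulin median was -0.0862 without chow control 4, and that of fatty acid oxidation 0.359 without high-fat control 1. The NRF2 (-0.0618) and ribosomal (0.0461) lists were not called with the unspliced share as a covariate. In the glucose storage list, which was not called, Ppp1r3g had -5.25, SE 0.86 (edgeR adjusted p = 0.00614), and Gckr, the glucokinase regulator, 0.69, SE 0.13 (0.0126). The calls of Hao2 and Ppp1r3g were lost with limma-voom. The list of markers of fat and pancreas was not called either, with a median of 0.92 over the 2 genes tested (0 rose, 0 adjusted over the list alone; camera adjusted p = 0.389, adjusted p = 0.711 with an estimated correlation).

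In knockout livers the diet comparison called 1516 genes, 748 higher and 768 lower. The acute phase list was not called (6 of 27 rose and 3 fell, 7 and 3 adjusted over the list alone; median -0.0139 but mean 0.568, camera adjusted p = 0.811; adjusted p = 0.956 with an estimated correlation). Among its genes that rose were Lcn2 by 3.90, SE 0.79 (edgeR adjusted p = 0.00749), Saa2 by 3.47, SE 0.59 (0.00359), Saa1 by 2.42, SE 0.55 (0.0131), and Orm2 by 2.73, SE 0.48 (0.0043). Cyp2b9 was at 85.6 ± 40.2 CPM against 0.166 ± 0.155 CPM (SD, n = 4 each; log2 fold change 9.04, SE 0.71, edgeR adjusted p = 3.2e-06). Plin4 rose by 3.10, SE 0.61 (0.00648), Gdf15 by 2.46, SE 0.37 (0.0015), and Col1a1 by 2.45, SE 0.35 (0.00129). Neat1, a nuclear noncoding RNA, rose by 2.77, SE 0.67 (0.0164), but by 0.54 with the unspliced share as a covariate, which ended its call, and its call was also lost without chow knockout 2. The neurotrophin receptor gene Ntrk2 rose by 2.40, SE 0.76 (0.0496), with a call lost in 11 of 16 leave-one-out fits. The calls of Plin4 and Ntrk2 were lost with the covariate too, and that of Ntrk2 with limma-voom and RLE size factors.

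Among genes that fell with the diet in knockouts, Fabp5 had -4.07, SE 0.59 (edgeR adjusted p = 0.00142), Adgrf1 -3.65, SE 0.65 (0.00439), and Csad -2.38, SE 0.46 (0.00641). The male-biased Serpina1e had -3.53, SE 0.62 (0.0043), Cyp4a12b -3.27, SE 0.55 (0.00311), and Cyp4a12a -2.42, SE 0.26 (0.000167). The major urinary proteins Mup14 and Mup7 had -2.77, SE 0.41 (0.00145), and -2.38, SE 0.52 (0.0106). G6pc, the last enzyme of glucose release, had -2.68, SE 0.56 (0.00906), and the heat shock gene Hspa1b -2.39, SE 0.52 (0.0101). The calls of Adgrf1 and G6pc were lost with the unspliced share as a covariate. The Saa, Mup, Cyp4a12 and Serpina1 genes belong to families with close copies, so their values are uncertain.

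In the knockout diet comparison 4135 genes had an unadjusted p under 0.05, and the groups did not overlap for 24.5% of genes against 2.86% by chance. The split was 1028 up and 447 down with upper-quartile factors and 1025 and 550 with length and GC offsets, and 1157 and 738 with no low-count filter, so the share of higher genes rests on the setting. Of the 1516 genes, 397 were called in all 16 leave-one-out fits. The count was 535 without chow knockout 2, 758 without chow knockout 4, 2914 without high-fat control 3, 708 without high-fat knockout 1, 465 without high-fat knockout 2 and 803 without high-fat knockout 3. It was 873 with the unspliced share as a covariate, which left 416 of the 1516. Without high-fat control 3 and chow knockout 1 together it was 3273.

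In knockouts, 17 of 44 lists passed camera between the diets, 7 higher and 10 lower, 0 of which passed with an estimated correlation. In the interferon list 16 of 28 genes rose, and 23 adjusted over the list alone, with a median of 0.91 (camera adjusted p = 1.53e-10; adjusted p = 0.367 with an estimated correlation). Gbp3, a guanylate-binding protein, rose by 1.28, SE 0.25 (edgeR adjusted p = 0.00648). In the fibrosis list 14 of 32 rose, and 19 adjusted over the list alone, with a median of 0.69 (adjusted p = 0.370 with an estimated correlation), and Col1a2 rose by 1.42, SE 0.27 (edgeR adjusted p = 0.00558). In the inflammatory list 7 of 22 rose, and 14 adjusted over the list alone, with a median of 0.92 (adjusted p = 0.367 with an estimated correlation). The chemokine Cxcl1 rose by 1.85, SE 0.33 (edgeR adjusted p = 0.00439), and the monocyte receptor Ccr2 by 1.74, SE 0.355 (0.00775). In the recruited macrophage list 8 of 17 rose and 1 fell, and 8 rose and 2 fell adjusted over the list alone, with a median of 1.05 (adjusted p = 0.723 with an estimated correlation). Gpnmb rose by 4.68, SE 0.92 (edgeR adjusted p = 0.00652). In the PPAR gamma list 4 of 7 rose, and 6 adjusted over the list alone, with a median of 1.90 (adjusted p = 0.704 with an estimated correlation), and the fat droplet gene Cidec rose by 4.17, SE 0.87 (edgeR adjusted p = 0.00893). The calls of Gpnmb and Cidec were lost with limma-voom with or without quality weights (adjusted p up to 0.129 and 0.145 over all alternatives). The list of markers of fat and pancreas was not called, with a median of 2.24 over the 2 genes tested (1 of 2 rose, 1 adjusted over the list alone; camera adjusted p = 0.662, adjusted p = 0.773 with an estimated correlation). Among the high-fat knockouts, both their mean log2 CPM (0.8341) and that of the PPAR gamma list (2.458) were lowest in knockout 3.

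The p53 (median 0.37, 3 of 27 rose, 8 up and 1 down adjusted over the list alone) and cell cycle lists (0.37, 1 of 27, 1) were higher too, with adjusted p = 0.222 and adjusted p = 0.723 with an estimated correlation. Without chow knockout 1 or 3, or high-fat knockout 1, the PPAR gamma, recruited macrophage and cell cycle lists were not called, nor the first 2 of them without high-fat control 1 or 3. Their leave-one-out medians were 1.27 to 2.75, 0.801 to 1.43 and 0.294 to 0.588. With the same genes tested as in all libraries, the cell cycle list was called without chow knockout 3. The highest PPAR gamma median was that without high-fat knockout 3, against 1.64 on the same voom scale with all libraries.

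Lower lists in the knockout diet comparison were led by male-biased genes, of which 21 of 26 fell, and 24 adjusted over the list alone, with a median of -1.54 (camera adjusted p = 9.99e-21; adjusted p = 0.0735 with an estimated correlation). In the ribosomal list 22 of 46 fell, and 41 adjusted over the list alone, with a median of -0.65 (adjusted p = 0.370 with an estimated correlation), and Rpl23 had -0.83, SE 0.14 (edgeR adjusted p = 0.00314). In the cholesterol list 10 of 26 fell, and 15 adjusted over the list alone, with a median of -0.72 (adjusted p = 0.370 with an estimated correlation). Cyp51, a sterol demethylase, had -1.46, SE 0.30 (edgeR adjusted p = 0.00767), and the sterol carrier Stard4 -0.92, SE 0.18 (0.00641). In the gluconeogenesis list 6 of 20 fell and 1 rose, and 7 fell and 2 rose adjusted over the list alone, with a median of -0.42 (adjusted p = 0.304 with an estimated correlation). Pck1, its rate-setting enzyme, had -1.27, SE 0.20 (edgeR adjusted p = 0.00229). Srebf1, in the fatty acid synthesis list that was not called (camera adjusted p = 0.108), rose by 1.43, SE 0.24 (edgeR adjusted p = 0.00309). That comparison uses the same chow knockouts in which Srebf1 was lower than in chow controls (log2 fold change -1.67), so the rise is not a separate finding.

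Also lower were the ER chaperone (median -0.36, 6 of 25 fell, 8 adjusted over the list alone), lipoprotein (-0.24, 5 of 27, 8) and mitochondrially encoded lists (-0.985, 2 of 8, 6), each with adjusted p = 0.370 with an estimated correlation. Bile acid genes had -0.20 (6 fell and 1 rose of 27, 10 and 1 adjusted over the list alone; adjusted p = 0.367 with an estimated correlation), and periportal genes -0.14 (5 and 1 of 24, 5 and 1; adjusted p = 0.481 with an estimated correlation). The respiratory chain list had -0.29 (1 of 42, and 0 adjusted over the list alone; adjusted p = 0.704 with an estimated correlation). The bile acid and periportal lists were not called without chow knockout 1, with leave-one-out medians of -0.24 to -0.0788 and -0.225 to -0.0907. On the voom scale the mitochondrially encoded median was -0.851, and -0.499 without chow knockout 1. Without high-fat knockout 3 the lipoprotein median went from -0.228 to -0.142 and the bile acid median from -0.16 to -0.104. The periportal median of -0.139 went to -0.225 without chow knockout 2 and -0.0907 without high-fat knockout 2. The respiratory chain (0.0607), bile acid (-0.125), periportal (-0.0219) and lipoprotein (-0.237) lists were not called with the unspliced share as a covariate.

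Calls were shared between comparisons as follows. The diet comparisons in controls and in knockouts use different libraries and shared 150 genes, 80 higher in both against 7.04 by chance and 70 lower in both against 6.8, with 0 in opposite directions. The knockout comparisons on chow and on the high-fat diet shared 1 gene, Degs1 (0.000976 by chance). Degs1 is the gene knocked out in both, so the chance value does not apply to it, and no other gene was shared. Across 9883 genes, which are not independent replicates, the covariance of the knockout effects on the 2 diets was 0.0266 and r was 0.26. Unchanged simulated groups gave a covariance of 9.44e-06. The simulations behind this paragraph drew each gene on its own, so they lack shifts that many genes share. The mean unspliced share was higher in knockouts on both diets. The covariance of the knockout effects therefore cannot be read as a knockout effect that recurs. Diet in knockouts shares the chow knockouts with knockout on chow, and the high-fat knockouts with knockout on the high-fat diet. Diet in controls and knockout on the high-fat diet both use the high-fat controls, with opposite signs. Gstm3 and Gna14 were called in both, in opposite directions, and 0 genes in the same direction. The covariance was -0.0236 against -0.0271 in simulated unchanged groups sharing those controls, a difference of 0.00345. Of the 262 genes called with diet in controls, 53.1% had the opposite sign in the high-fat knockout, against 71.5% in a simulation that kept only the diet effects. The simulated genes were not edgeR calls but the same number with the largest difference relative to spread. The shares therefore rest on unlike selections, and no conclusion is drawn from their difference. Over 6 ways to split the controls, the covariance ran from -0.0175 to 0.0967.

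The interaction tests whether the knockout effect differed between the diets. edgeR called 0 genes, with 1615 at an unadjusted p under 0.05, while DESeq2 called 71, limma-voom 0 and limma-voom with quality weights 9. The Degs1 interaction, chosen after its values were seen, was -0.07, SE 0.23 (edgeR adjusted p = 0.929). The smallest p values belonged to Fbxo30 (-1.04, SE 0.19), Uba7 (1.21, SE 0.23), the enzyme that activates ISG15, and Oasl1 (1.30, SE 0.25). Col1a1 had 2.499, SE 0.483, Csf1, a macrophage growth factor, 1.13, SE 0.23, Igsf8 1.12, SE 0.23, and Rnf2 -0.90, SE 0.18. Gstm3 had 2.10, SE 0.43, Parp10 1.23, SE 0.26, and Rnf213 1.02, SE 0.22. Srebf1 had 1.47, SE 0.33, and Phlda3 2.39, SE 0.53. All of these other than Degs1 had edgeR adjusted p = 0.211. The count was 1 without chow control 2 and 1 without high-fat knockout 4.

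For the interaction 20 of 44 lists passed camera, 10 higher and 10 lower on the high-fat diet relative to chow, 0 of them with an estimated correlation. The interferon list had a median difference of 0.95 (0 of 28 genes past the test over all genes, 16 adjusted over the list alone) and the fibrosis list 0.88 (0 of 32, 14). The inflammatory list had 0.86 (0 of 22, 1) and the p53 list 0.29 (0 of 27, 3). Each had adjusted p = 0.292 with an estimated correlation. Mitochondrially encoded messages had -1.08 (0 of 8, 3; adjusted p = 0.337 with an estimated correlation) and the respiratory chain -0.36 (0 of 42, 0; adjusted p = 0.575 with an estimated correlation). On the voom scale the respiratory chain median went from -0.307 to -0.114 without high-fat control 3.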

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

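Tests of transcript length and GC content for both list patterns, and of the unspliced share for Srebf1, were chosen only after the result was seen. A Dixon test over groups of 4 livers marked 31 of 388 groups in library measures and named genes, where chance marks about 1 in 20. The set of named genes was shortened for length after these marks had been seen, and the longer set gave 48 of 536.

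Chow knockout 1 lay far from its group in the rRNA share, 0.424% against 0.00745% to 0.0146%. It also did so for mt-Co1 (20700 CPM), Cyp3a59 (35.5), Adgrf1 (17.7), Cyp4a12b (98.8), Irs2 (43.8), Neat1 (145) and Mup7 (2030). High-fat knockout 1 did so for Gbp3 (13.8 CPM), Tnfaip3 (13.4), Fabp5 (6.45), Ntrk2 (35.6), Hspa1b (4.26), Cidec (50.7, against 1.17 to 8.66) and Igsf8 (10.6). High-fat knockout 3 did so for Serpina1e (975 CPM), Prss8 (2.24) and Mup14 (48.1). High-fat knockout 4 did so for mt-Co1 (13300 CPM), Mki67 (6.73) and Cyp51 (177), and high-fat knockout 2 for Cygb (9.93 CPM) and the unspliced share (0.191%). High-fat control 3 did so for Cers2 (357 CPM), Phlda3 (1.15) and Ndufv2 (173), high-fat control 2 for Ntrk2 (23.9), chow control 3 for Cyp17a1 (18) and Tgm1 (35.9), and chow knockout 4 for Phlda3 (1.91).

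Chow knockout 3 had 31083 genes with a count against 16510 to 18963 in the other chow knockouts. Of the features too low to be tested it had counts on 16752, against up to 5822 in controls and 6751 in the other knockouts. These features held 0.324% of its counts.

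The knockout effect differed between the diets by camera for 20 lists, none of them with an estimated correlation. Camera adjusted p was 1.39e-13 for interferon, 5.04e-12 for fibrosis, 4.21e-08 for the respiratory chain, 2.57e-07 for inflammatory genes, 3.49e-06 for fatty acid oxidation and 5.5e-06 for ribosomal proteins. It was 4.55e-05 for mitochondrially encoded messages, 0.000125 for male-biased genes, 0.000404 for xenobiotic cytochromes, 0.000955 for fatty acid synthesis, 0.00126 for cell cycle and 0.00355 for bile acid genes and for Kupffer cell markers. It was 0.00468 for p53 targets, 0.0054 for fetal liver genes, 0.00927 for lipoproteins, 0.0216 for lymphocyte markers, 0.0247 for PPAR alpha targets, 0.028 for periportal genes and 0.0306 for recruited macrophage markers. The call was lost in 6 of 16 leave-one-out fits for lymphocyte and recruited macrophage markers (medians 0.316 to 1.34 and 0.196 to 0.929), 5 for PPAR alpha targets (-0.477 to -0.225) and periportal genes (-0.276 to -0.0835) and 2 for Kupffer cell markers (0.292 to 0.767). It was lost in 1 for p53 targets (0.265 to 0.409, without high-fat control 1) and, without high-fat control 3, for lipoproteins (-0.383 to -0.0862) and ribosomal proteins (-0.483 to -0.0469). Without high-fat control 3 the medians also moved, on the voom scale, from -0.307 to -0.114 for the respiratory chain, -0.32 to -0.186 for fatty acid oxidation, -0.387 to -0.22 for xenobiotic cytochromes, 0.31 to 0.498 for fatty acid synthesis and 0.577 to 1 for cell cycle. Medians also moved by over 1.5 times without other libraries. They were 0.532 and 0.537 for fatty acid synthesis without chow knockout 4 and high-fat knockout 3, -0.236 for xenobiotic cytochromes without chow knockout 1 and -0.181 for lipoproteins without chow control 4 (-0.287 with all). They were 0.329 for cell cycle without high-fat control 1, 0.334 for fetal liver genes without high-fat knockout 1 (0.572) and -0.483 for ribosomal proteins without high-fat control 2 (-0.318). For PPAR alpha targets the value was -0.477 without high-fat control 1 (-0.31). With the same genes tested as in all libraries, calls were lost without high-fat control 1 for cell cycle and fetal liver genes, without high-fat knockout 2 for recruited macrophage markers and without high-fat control 2 for periportal genes as well.

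Other splits of the livers bear on the counts. For knockout on the high-fat diet 1 of 35 splits, the real one, gave 16 genes and the highest other gave 1. This passes 0.05 only at the smallest share that 35 splits allow and without adjustment over the counts tested, so chance is not firmly excluded. The same holds for diet in knockouts (1 of 35, 1516 genes, highest other 0). It also holds for diet in controls (1 of 35, 262 genes), though the highest other split, chow control 1 with high-fat controls 1, 2 and 4 against the rest, called 181. That split exchanges high-fat control 3 with chow control 1, while exchanging it with chow control 2, 3 or 4 called 15, 0 and 2. The sides of that split also have log2 ratios of the clock genes Dbp and Arntl that do not overlap (-3.04 to 2.24 against 2.5 to 4.54). Their unspliced shares do not overlap either (0.0411% to 0.164% against 0.0218% to 0.0369%), so what sets the sides apart stays open. For knockout on chow 3 of 35 splits gave 2 genes or more (highest other 4), so chance is not excluded. For the interaction the real count was 0, which 100 of 100 splits reach by construction (highest other 4), so this says nothing about chance. For lists chance is not excluded in any comparison. As many lists were called in 29 of 35 splits for knockout on chow (8, highest other 16), 17 of 35 for knockout on the high-fat diet (18, 26), 26 of 35 for diet in controls (11, 20), 14 of 35 for diet in knockouts (17, 22) and 8 of 100 for the interaction (20, 25).

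The respiratory chain and ribosomal protein lists were lower in the high-fat knockout, which also had the higher unspliced share. Within groups, the list means fell as the log2 unspliced share rose, with r = -0.868 and rho = -0.659 (permutation p = 0.00202 and 0.00239, adjusted 0.0101 and 0.00598 over 5 relations, n = 16) for the respiratory chain. For ribosomal proteins r was -0.903 and rho -0.844 (permutation p = 0.00706 and 0.00041, adjusted 0.0176 and 0.00205, n = 16). High-fat control 3 and high-fat knockout 2 had the shares farthest from the median of all livers. Without these libraries r was -0.729 for the respiratory chain and -0.807 for ribosomal proteins. The group means removed there still included them, so their influence was not fully taken out. With length and GC offsets the medians, on the voom scale, went from -0.539 and -0.481 to -0.183 and -0.139 and stayed past camera at the preset correlation. Most of each median went, so whether a length or GC trend is the whole cause stays open. With the unspliced share as a covariate the medians were -0.193, still past camera, and -0.0248, no longer past it because the shift itself shrank. RNA composition of the libraries may account for much of this pattern, and a genotype effect stays open.

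The fibrosis, interferon and inflammatory lists were higher in the high-fat knockout. The unspliced share, which would need a positive relation, had r = -0.0758, -0.482 and -0.385 within groups (permutation p = 0.716, 0.217 and 0.157, adjusted 0.716, 0.271 and 0.262, n = 16; rho -0.0941, -0.247 and -0.359), and with length and GC offsets the medians went on the voom scale from 0.735, 0.817 and 0.753 to 0.558, 0.973 and 0.795. A lower share of hepatocytes would raise markers of all other cells alike, but the fibrosis list rose over the sinusoidal endothelial list by 0.815 (exact permutation p = 0.0286, the smallest possible, n = 4 each). This covers the fibrosis list only, and a change in the mix of the other cells was not tested. A response to loss of Degs1 under the high-fat diet is a candidate explanation, as a hypothesis found and tested on the same livers, and neither chance for the list count nor an unrecorded difference in housing or collection is excluded.

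Srebf1 was lower in the chow knockout, with a log2 fold change of -1.67, SE 0.24. Srebf1 varies with feeding and time of day. With the log2 ratio of the clock genes Dbp and Arntl as a covariate its log2 fold change was -1.58, SE 0.24 (edgeR adjusted p = 0.0381). A linear trend with this ratio thus accounted for little of the fall. A single ratio cannot fix the time of day, so clock phase stays open as a cause. With the unspliced share as a covariate the fold was -1.67, SE 0.27 (edgeR adjusted p = 0.0543), so the call ended because the error grew while the fold stood still. Feeding state before collection may also contribute and was not tested, and with 3 of 35 splits giving as many genes chance is open too.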

How the results depend on the processing

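The alternatives with the unspliced share, with length and GC offsets, and without the 2 libraries standing apart were chosen only after the result was seen. Over named genes that were called, 0 values reversed under any alternative. Other than Degs1, these genes were named for large fold changes or small p on the same livers, so reversals were unlikely from the start. The call weakened in 1 of 18 values under alternatives chosen in advance other than leaving out a library for knockout on chow, 16 of 144 for knockout on the high-fat diet, 17 of 259 for diet in controls and 7 of 279 for diet in knockouts. Fits of only the groups compared gave 1, 15, 9 and 0 of these. With each library left out in turn it weakened in 12 of 32, 106 of 256, 45 of 464 and 12 of 496, and under alternatives added after seeing the data in 3 of 6, 33 of 48, 3 of 87 and 5 of 93. Where a count below moved, the cause was not tested, except that stricter thresholds pass fewer genes by construction. Depth limits what is seen of genes near 0.129 to 0.251 CPM, where 3 counts lie.

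Counts of genes called, given for knockout on chow (2), knockout on the high-fat diet (16), diet in controls (262), diet in knockouts (1516) and the interaction (0), moved by over 1.5 times as follows. With DESeq2 they were 39, 578, 719 and, for the interaction, 71. With no low-count filter they were 308, 964, 992 and, for the interaction, 259. With limma-voom and quality weights they were 4, 287, 790, 4345 and 9, and limma-voom gave 31 for knockout on the high-fat diet. Upper-quartile factors gave 34 there. Fits of only the groups compared gave 1, 1, 75 and 2793. An adjusted p under 0.01 left 0, 3, 56 and 286, and an absolute log2 fold change of at least 1 left 640 for diet in knockouts. With the unspliced share as a covariate they were 0, 0, 1157 and 873, and without the 2 libraries standing apart 1219 for diet in controls and 3273 for diet in knockouts.

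Leaving out each library in turn gave 0 to 4 genes for knockout on chow, 3 to 31 for knockout on the high-fat diet, 100 to 955 for diet in controls, 465 to 2914 for diet in knockouts and 0 to 1 for the interaction. The Degs1 log2 fold change on chow ran from -1.17 to -1.12, and with the unspliced share as a covariate it was -0.956. On the high-fat diet it was -1.23 with only the groups compared (edgeR adjusted p = 0.138) and -0.917 with the unspliced share (0.0535), and its call was lost in both.

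Camera with an estimated correlation called 0 lists in each of the 5 comparisons, and fry called 0, 8, 1, 11 and 0. With a library left out and the genes kept that were tested in all libraries, added after seeing the data, called lists were lost in 14 of 128, 10 of 288, 7 of 176, 14 of 272 and 31 of 320 fits, against 17, 8, 7, 15 and 27 with the filter run again. For knockout on chow, 4 lists were called with the unspliced share as a covariate and 4 with length and GC offsets. The ribosomal list on chow reversed to a median of 0.15 with the unspliced share as a covariate, and the cause was not tested. The knockout calls shared between diets numbered 7 in the same direction and 1 in opposite directions with DESeq2, and 0 with only the groups compared. Genes called in opposite directions with diet in controls and with knockout on the high-fat diet numbered 40 with DESeq2 and, with the controls split, 20 with replicates 1 and 2 for diet (against 649 in the same direction), 3 with 1 and 4 (against 2), 0 with 2 and 4 (against 2) and 0 with 1 and 3, 2 and 3, or 3 and 4 (against 0).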

Other observations

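Most lists of other cell types did not pass camera between genotypes on the high-fat diet. Median log2 fold changes there were 0.77 for lymphocyte markers (camera adjusted p = 0.0651), 0.21 for Kupffer cell markers (0.256), -0.0467 for sinusoidal endothelial markers (0.645), 0.29 for cholangiocyte markers (0.461) and -0.69 for blood markers (0.0964). The lymphocyte value rests on high-fat knockout 3, with a mean log2 CPM of 2.176 against 0.1315 to 0.4001 in the other high-fat knockouts. On the voom scale, with the same genes tested, its median went from 0.526 to 0.141 without that library (camera adjusted p = 0.524), and it was 0.375 without abundant features. For neutrophil markers the median was -0.20 (adjusted p = 0.914 with an estimated correlation). The 2 tested markers of fat and pancreas had a median of -0.435 (0.174). On the same diet the lists of ceramide turnover (median -0.02, camera adjusted p = 0.261), circadian clock (0.03, 0.833), fatty acid uptake (-0.12, 0.0968) and membrane lipid synthesis (-0.18, 0.0503) were not called either. Nor were triglyceride synthesis and lipid droplets (median 0.00498) or the integrated stress response (0.22), each with adjusted p = 0.914 with an estimated correlation.

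Per liver, mean list scores gave exact permutation tests with little room. Libraries of the groups did not overlap for 4 of 44 lists for knockout on chow, 8 for knockout on the high-fat diet, 7 for diet in controls and 14 for diet in knockouts, against 2.86% of single genes by chance. The smallest adjusted exact p was 0.315, 0.157, 0.18 and 0.0899.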
